A study of Rattus norvegicus with 62 samples.

How the data were processed

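Expression was measured with an Affymetrix rat array in 62 samples of cardiac muscle of male Wistar rats, with 1 array per sample. Per the labels, total RNA was prepared with a column kit that includes a DNase step, was labelled with biotin by a 1-cycle protocol, and came from tissue kept in RNAlater, an RNA stabilising solution. The deposited values are intensity signals on a linear scale, 1 per probe set and array, and per the submitters' processing notes GCOS and MAS5 were used, with versions not given in the sources used here. A probe set is a group of short probes for 1 transcript, and MAS5 reduces their brightness to 1 signal for each array separately. The deposited table held 31099 probe sets, of which 57 control probe sets were left out, leaving 31042.

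The arrays turned out not to share a common scale. The 2% trimmed mean of the deposited signals ran from 83.5 to 247 between arrays, a ratio of 2.96, the median from 31.2 to 87.2 and the highest signal from 17800 to 21400, while the lowest signal of the table was 0.016. The plan written before the data were examined assumed signals scaled to a common level, took their log2 as the main values and named quantile normalization between arrays as an alternative. Because of the unequal scale the roles were exchanged before any comparison between groups was computed: log2 signals were quantile normalized for the main values, and the signals as deposited became an alternative. All differences below are therefore relative to the other probe sets. On the deposited scale the median difference of all tested probe sets for 80 mg/kg against vehicle was 0.37, −0.30, −0.21 and 0.04 (log2) at 6, 24, 168 and 336 h, for 10 mg/kg against vehicle −0.01, −0.36, −0.25 and 0.14, and for 80 against 10 mg/kg 0.38, 0.06, 0.04 and −0.10. With the arrays scaled by their medians alone it passed 0.1 in size only at 24 h, at −0.17 for 80 mg/kg and −0.13 for 10 mg/kg against vehicle.

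Probe sets were kept where the mean log2 signal over all arrays lay at or above the 40th percentile, a level of 5.03, which left 18625. Gene names came from the platform's annotation table, in which 20832 probe sets had 1 gene and 436 several, and 20764 gene identifiers were matched in a RefSeq gene table, with 0 symbols replaced. Of the tested probe sets 14260 had 1 gene (10557 genes in all), 338 had several and 4027 had none listed. No gene was named from a probe set with several genes. Coordinates were not used.

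Groups were taken from the labels as 12 combinations of dose (0, 10 or 80 mg/kg/day during 14 days) and sampling time (6, 24, 168 or 336 h after the final treatment). The labels do not state that each sample of a group came from its own animal, so p-values measure the spread between these samples. No pair of the 62 arrays held identical values, and rank correlations between arrays of a group lay between 0.885 and 0.952. A linear model with a mean for each of the 12 groups was fitted with limma 3.58.1 in R 4.3.3, with 50 residual degrees of freedom, 2.36 prior degrees of freedom and a median residual SD of 0.297 (log2). The 12 contrasts were each dose against vehicle and 80 against 10 mg/kg at each time. Moderated F tests asked whether the effect of 80 mg/kg, the effect of 10 mg/kg and the level in vehicle differed between the 4 times. The p-values were two-sided and were adjusted by Benjamini-Hochberg over the probe sets of each test, and a probe set was called at an adjusted p under 0.05. Vehicle arrays served as the background in each comparison, and overlaps between doses were set beside 1000 simulations of unchanged groups that shared the same vehicle arrays.

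At the same stage as the plan, 29 gene lists with 511 members were fixed, 15 for pathways and 14 for cell types, of which 364 distinct members were measured. Each was tested with camera of limma (preset correlation 0.01, a test against the other genes) on the brightest probe set of each gene, with camera with an estimated correlation and fry (which tests whether members move on balance in 1 direction) beside it. The 27 lists with at least 5 measured members gave 324 tests adjusted together. Camera called 27 of these tests and 0 kept the call with an estimated correlation, where the smallest adjusted p was 0.0536. The lists for red blood cells and brown adipocytes had too few measured members to be tested.

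Genes named below followed a rule fixed at that stage. For each pairwise comparison it took up to 6 genes with the largest rise and 6 with the largest fall among called probe sets with 1 gene, up to 4 called members of each called list, and a fixed set of metabolic and cardiac genes whatever their p, among which Acot1, Angptl4 and Adipoq had no kept probe set with 1 gene. For the F tests it took the 8 smallest p-values. Other genes named, among them list members that passed only adjusted over the list alone, were chosen after their values were seen.

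The procedure was tested on simulated data, with 50 probe sets changed at each of 4 log2 sizes (0.5, 1, 2 and 3) among the 18625. Noise was drawn independently for each probe set and array, with 1 spread per probe set and no array clusters. The shares of false calls therefore do not describe arrays that form clusters or differ in spread. For 80 mg/kg against vehicle it recovered 12, 39, 45 and 50 at 6 h (7 of 153 calls false), 16, 42, 48 and 49 at 24 h (4 of 159), 17, 39, 48 and 50 at 168 h (14 of 168), and 15, 36, 45 and 50 at 336 h (8 of 154). The number of arrays limits the precision.

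Alternatives in that plan were the deposited scale, no filter, a stricter filter at the 60th percentile, a pseudocount of 5.38 signal units, array weights, a trended robust prior, the replicate number as a block, 1 probe set per gene, only the arrays of the groups or times compared, and leaving out each array in turn. Alternatives chosen after seeing the data were median scaling, the array cluster as a block, control probe covariates, the Myl7 level as a covariate, leaving out arrays with a high Myl7 level (above 9), and leaving out arrays with a high actin 3' to 5' difference (above 1.5). Array clusters came from k-means with 3 clusters and 50 starts on the first principal components. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.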

Results

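Gene expression was measured in cardiac muscle of male Wistar rats, an outbred laboratory strain, after oral treatment with rosiglitazone. Rosiglitazone is a glucose-lowering thiazolidinedione that activates PPAR gamma, a nuclear receptor driving fat cell differentiation and lipid storage, and the series asks how it affects the heart. Rats received vehicle, 10 mg/kg or 80 mg/kg daily during 14 days, and by the labels hearts were sampled 6, 24, 168 and 336 h after the final dose. In the order of these times there were 4, 6, 5 and 5 vehicle arrays, 5, 5, 5 and 6 arrays at 10 mg/kg, and 5, 5, 6 and 5 arrays at 80 mg/kg. Values are log2 signals after quantile normalization, differences are log2 differences of group means with their standard error (SE), and 18625 probe sets were tested with limma.

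The arrays also differed in markers of tissue and of RNA quality. The atrial myosin light chain gene Myl7 lay between 9.32 and 12.9 in 10 arrays and at most at 8.71 in all others. The atrial genes Myl4 and Nppa were also higher in these than in all other arrays, except for Nppa in replicate 5 of 10 mg/kg at 6 h, at 11.05. Those arrays were 1 of 4 vehicle, 4 of 5 at 10 mg/kg and 2 of 5 at 80 mg/kg at 6 h, and 3 of 5 at 80 mg/kg at 24 h, with 0 at 168 and 336 h. A high actin 3' to 5' difference, a sign of RNA breakdown, was found in 3 arrays, 1 of vehicle at 6 h and 2 of vehicle at 24 h. The first principal components (14.4% and 8.94% of the variance) parted the arrays into 3 clusters of 21, 21 and 20 arrays. Each cluster held all 3 dose levels (7, 7 and 7 arrays, 6, 7 and 8, and 7, 7 and 6, for vehicle, 10 and 80 mg/kg), but all 16 arrays of 336 h lay in the second. Within a time the clusters were uneven between the groups compared: at 24 h they held 1, 0 and 5 vehicle arrays and 2, 2 and 1 of 80 mg/kg, and at 6 h 3, 0 and 1 of vehicle and 2, 0 and 3 of 80 mg/kg. The hexokinase 3' to 5' control difference ran from 1.38 to 1.97, from 1.42 to 2.45 and from 2.09 to 6.08 in the 3 clusters.

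At 6 h after the last dose, hearts of rats given 80 mg/kg had higher levels of genes for lipid handling by adipose tissue and capillaries. Rbp7, a retinol-binding protein of adipose tissue and endothelium, rose from 7.96 ± 0.44 (SD, n = 4) in vehicle to 10.89 ± 0.24 (SD, n = 5), a 7.62-fold difference (log2 2.93, SE 0.43, limma adjusted p = 6.94e-05). Fabp4, the fatty acid binding protein of adipocytes and capillary endothelium, rose 2.01-fold (95% interval 1.64 to 2.46, adjusted p = 6.94e-05). Gpihbp1, the endothelial anchor of lipoprotein lipase, rose by 1.48 (SE 0.28, adjusted p = 0.0143). Slc2a3, a glucose transporter, rose by 1.21 (SE 0.19, adjusted p = 0.000555). Adamts4, a proteoglycan-degrading protease, rose by 1.83 (SE 0.38) and Zfp131, a zinc finger protein, by 1.77 (SE 0.37). Rubcn, an inhibitor of autophagy, fell by 0.58 (SE 0.12), these 3 at an adjusted p of 0.0314. The vehicle means of Adamts4 (3.42) and Zfp131 (4.01) lay below the filter level of 5.03, so the sizes of their rises are uncertain. Rubcn was at −0.18 on the deposited scale (adjusted p = 0.642), where the median of all tested probe sets was 0.37. All 5 treated arrays lay on the same side of the vehicle mean for each of these genes. Another kept probe set of Zfp131 had the opposite sign (−0.07). In all, 10 probe sets changed, 8 higher and 2 lower, and 1239 had an unadjusted p under 0.05. The list for fatty acid uptake and storage was higher as a group, with 18 of 21 measured members positive (median 0.14, camera adjusted p = 0.00042; adjusted p = 0.134 with an estimated correlation). Of its members Gpihbp1 passed over all probe sets. Adjusted over the list alone 3 passed, namely Gpihbp1, the fatty acid transporter Cd36 and the monoglyceride lipase Mgll. Immediate early genes, which respond within minutes to stimulation, had 9 of 12 members positive (median 0.27, adjusted p = 0.0443; adjusted p = 0.795 with an estimated correlation). Of these 0 passed limma over all probe sets and 2, Fos and Nr4a1, adjusted over the list alone. That list call was lost without vehicle replicate 1 or 3 or 80 mg/kg replicate 4, 5 or 6 (adjusted p up to 0.402). It was also lost with no filter (0.117), with probe sets averaged per gene (0.077) and with the replicate number as a block (0.0916). The count of 10 became 29 without vehicle replicate 3, 5 without vehicle replicate 1 or 6, 3 without 80 mg/kg replicate 1 and 6 without 80 mg/kg replicate 2, 4 or 6. Leaving out vehicle replicate 1, 5 or 6 or 80 mg/kg replicate 1, 2, 4 or 6 ended the call of at least 1 of Adamts4, Zfp131, Gpihbp1 and Rubcn (adjusted p up to 0.151, 0.289, 0.127 and 0.198). The count was 6 on the deposited scale (6 higher, 0 lower) and 9 with median scaling (9 higher, 0 lower). It was 5 with no filter or with array weights, 16 with the array cluster as a block, 5 without the high-Myl7 arrays and 6 without the high-actin arrays. It was 0 in limma with the 6 h arrays alone (897 at an unadjusted p under 0.05).

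At 24 h the same lipid genes were higher at 80 mg/kg, and genes of the circadian clock differed from vehicle. Rbp7 rose by 2.95 (SE 0.38, adjusted p = 7.65e-06), Gpihbp1 by 1.70 (SE 0.26, adjusted p = 8.87e-05) and Fabp4 by 0.73 (SE 0.13, adjusted p = 0.00374). Aqp1, the water channel of capillary endothelium and red blood cells, fell by 0.81 (adjusted p = 8.87e-05), a gene named here after its value was seen. The clock repressor Bhlhe41 rose from 7.89 to 8.78, a difference of 0.90 (SE 0.13, adjusted p = 8.87e-05). Its relative Bhlhe40 rose by 1.44 (SE 0.30) and Dbp, a transcription factor driven by the clock, by 1.36 (SE 0.28), both at an adjusted p of 0.0187. Klf13, a transcription factor, rose by 1.34 (SE 0.31, adjusted p = 0.0437) and Kif3a, a kinesin motor subunit, by 1.72 (SE 0.37, adjusted p = 0.0231). Sh3pxd2b, an adaptor of podosomes, fell by 1.67 (SE 0.37, adjusted p = 0.0278), Mcm6, a subunit of the replication helicase, by 1.46 (SE 0.30, adjusted p = 0.0187). Eola2 fell by 1.24 (SE 0.27, adjusted p = 0.0231), Lsm11 by 0.91 (SE 0.21, adjusted p = 0.05). Palmd fell by 0.84 (SE 0.18, adjusted p = 0.0231) and Arhgap15 by 0.82 (SE 0.18, adjusted p = 0.0287). All 5 treated arrays lay on the same side of the vehicle mean for each, except 4 of 5 for Lsm11. Kif3a (−0.18), Eola2 (0.14) and Palmd had another kept probe set of opposite sign. Means lay below the filter level of 5.03 in vehicle for Kif3a (3.89) and Klf13 (4.97) and at 80 mg/kg for Sh3pxd2b (3.94), Mcm6 (4.67), Eola2 (4.63) and Arhgap15 (4.49), so the sizes of these differences are uncertain. Without the high-Myl7 arrays Mcm6 was at −0.48 (adjusted p = 0.652) and Sh3pxd2b at −0.84 (adjusted p = 0.496).

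Of 15 measured clock genes at 24 h, 7 were positive and 8 negative. Their median was −0.02 and their mean 0.26, and camera called the list higher (adjusted p = 0.00772). The adjusted p was 0.0649 with an estimated correlation and 0.0639 with probe sets averaged per gene. Over all probe sets 3 members rose, Bhlhe41, Bhlhe40 and Dbp. Adjusted over the list alone 7 rose, Per2, Bhlhe41, Bhlhe40, Nr1d1, Dbp, Nr1d2 and Tef, and 3 fell, Bmal1, Clock and Cry1. Bmal1, a core activator that peaks opposite to Dbp, had a mean of 6.35 at 80 mg/kg and 7.36 in vehicle. The atrial list was higher (5 of 7 members positive, median 1.71, adjusted p = 0.00847; adjusted p = 0.527 with an estimated correlation). Of its members 0 passed limma over all probe sets and 3, Nppa, Myl4 and Myl7, adjusted over the list alone. It was no longer called without 80 mg/kg replicate 2, 4 or 5 (adjusted p up to 0.124), and Myl7 was high in 3 of the 5 treated arrays. The adipocyte cell type list had 4 of 5 members positive (median 0.15, adjusted p = 0.0346; adjusted p = 0.214 with an estimated correlation). Of these 1, Fabp4, passed both over all probe sets and adjusted over the list alone. The call was lost without vehicle replicate 3 or 4 or 80 mg/kg replicate 2, 4 or 5 (adjusted p up to 0.0851) and with probe sets averaged per gene (0.152).

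The 24 h comparison called 26 probe sets, 14 higher and 12 lower, with 2065 at an unadjusted p under 0.05, and this count depended on the processing. It was 1 on the deposited scale, which was Rbp7 (1 higher, 0 lower). It was 214 with median scaling, 15 higher and 199 lower, with 21 of the 26 among them. It was 48 with array weights, 12 with the array cluster as a block (9 of the 26 among them), 11 with control probe covariates and 11 with the Myl7 level as a covariate. It was 8 without the high-actin arrays and 6 with the 24 h arrays alone. Without the high-Myl7 arrays it was 24, of which 7 were among the 26. It was 7 without 80 mg/kg replicate 2, 14 without 80 mg/kg replicate 4, and 13, 46 and 10 without vehicle replicate 1, 2 and 4. Rbp7, Gpihbp1 and Bhlhe41 kept their call when any 1 array was left out and with the array cluster as a block. With that block Dbp was at 1.32 (1.36 without it, adjusted p = 0.0542 with it) and Bhlhe40 at 0.84 (1.44 without it, adjusted p = 0.262 with it). Leaving out any single array ended the call of at least 1 of the other genes the rule named at 24 h. The highest adjusted p was 0.0521 for Fabp4 (without 80 mg/kg replicate 2), 0.0783 for Dbp (without vehicle replicate 4) and 0.207 for Lsm11 (without 80 mg/kg replicate 6).

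At 168 h Rbp7 stood 13.6-fold above vehicle at 80 mg/kg (log2 3.76, SE 0.38, adjusted p = 1.9e-09), Gpihbp1 5.35-fold (log2 2.42, SE 0.26, adjusted p = 4.26e-09) and Fabp4 1.92-fold (log2 0.94, SE 0.13, adjusted p = 1.24e-05). Aqp1 fell from 10.95 in vehicle (n = 5) to 9.69 ± 0.07 (SD, n = 6), a difference of −1.25 (SE 0.12, adjusted p = 5.45e-10). Its other kept probe set gave −1.14. Fabp5, a second fatty acid binding protein, rose by 0.78 (SE 0.16, adjusted p = 0.0234), Hrct1 by 0.51 (SE 0.11, adjusted p = 0.0306) and Ggta1, a galactosyltransferase, by 0.49 (SE 0.11, adjusted p = 0.039). Cytl1, a secreted cytokine-like protein, fell by 0.78 (SE 0.16, adjusted p = 0.0174). All 6 treated arrays lay on the same side of the vehicle mean for each. Of 23 measured genes of fatty acid oxidation 22 were negative (median −0.16, camera adjusted p = 1.2e-08; adjusted p = 0.106 with an estimated correlation). Of these 0 passed limma over all probe sets and 4, Eci1, Acadm, Decr1 and Hadh, adjusted over the list alone. Their differences were small, with Decr1, a reductase for unsaturated fatty acids, at −0.52 and Acadm, the medium-chain acyl-CoA dehydrogenase, at −0.24. The fetal gene program and wall stress list had 12 of 15 members positive (median 0.18, adjusted p = 0.0443; adjusted p = 0.527 with an estimated correlation). In it 0 passed limma over all probe sets and 0 adjusted over the list alone. The call was lost with no filter (0.111), without vehicle replicate 2 or 3 and without any of the 80 mg/kg replicates 1 to 5 (adjusted p up to 0.191). There were 10 called probe sets, 7 higher and 3 lower, with 1014 at an unadjusted p under 0.05. The count was 5 without vehicle replicate 5, 3 on the deposited scale, 6 with no filter and 19 with the array cluster as a block. Leaving out any single array ended the call of at least 1 of Fabp5, Hrct1, Ggta1 and Cytl1 (adjusted p up to 0.137, 0.183, 0.165 and 0.108).

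At 336 h, the last time sampled, the genes called at 80 mg/kg included the extracellular matrix genes Ccn2, Lox and Fn1. The calls of Lox and Fn1 depended on single arrays. Rbp7 rose from 7.74 to 11.84, a 17.2-fold difference (log2 4.10, SE 0.40, adjusted p = 4.23e-10). Gpihbp1 rose 6.16-fold (log2 2.62, SE 0.27, adjusted p = 1.22e-09) and Fabp4 2.06-fold (log2 1.04, adjusted p = 2.03e-06). Aqp1 fell from 11.37 to 9.67 ± 0.20 (SD, n = 5), a difference of −1.70 (SE 0.13, adjusted p = 2.92e-14), with −1.80 at its other kept probe set. Akap12, a scaffold for protein kinase A, rose by 1.12 (SE 0.15, adjusted p = 1.73e-06), Tnfsf10, the death ligand TRAIL, by 1.14 (SE 0.16, adjusted p = 1.05e-05). Cxcl9, an interferon-induced chemokine, rose by 1.24 (SE 0.26, adjusted p = 0.00725) and Fancd2os by 1.54 (SE 0.37, adjusted p = 0.0415), the last from a vehicle mean of 4.01 below the filter level, so its size is uncertain. Pla2g2a, a secreted phospholipase, fell by 1.68 (SE 0.34, adjusted p = 0.00641), Cyp26b1, which degrades retinoic acid, by 1.20 (SE 0.26, adjusted p = 0.0122). Myrip fell by 0.92 (SE 0.15, adjusted p = 0.000165), with 1 of its 2 other probe sets of opposite sign. Ggt5 fell by 0.91 (SE 0.15, adjusted p = 0.000247) and Slc22a3, an organic cation transporter, by 0.78 (SE 0.18, adjusted p = 0.0285). All 5 treated arrays lay on the same side of the vehicle mean for each.

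Extracellular matrix genes were higher as a group at 336 h at 80 mg/kg, with 27 of 29 measured members positive (median 0.22, camera adjusted p = 2.56e-06; adjusted p = 0.472 with an estimated correlation). Of these 3 rose both over all probe sets and adjusted over the list alone. These were Ccn2, a matricellular growth factor (0.98, SE 0.18, adjusted p = 0.00269), Lox, which crosslinks collagen (0.73, SE 0.17, adjusted p = 0.0244), and Fn1, fibronectin (0.86, SE 0.21, adjusted p = 0.0415). Cell cycle genes were higher with 19 of 21 positive (median 0.34, adjusted p = 0.000104; adjusted p = 0.25 with an estimated correlation). Of these 0 passed limma over all probe sets and 0 adjusted over the list alone. Genes of fatty acid oxidation were lower, with 21 of 23 negative (median −0.17, adjusted p = 2.89e-07; adjusted p = 0.134 with an estimated correlation). In this list 0 passed limma over all probe sets and 4, Eci1, Acadm, Decr1 and Acadvl, adjusted over the list alone, with Eci1 at −0.33 and Decr1 at −0.41. There were 54 called probe sets, 46 higher and 8 lower, with 1298 at an unadjusted p under 0.05. The count was 5 on the deposited scale (3 higher, 2 lower), 232 with array weights (153 higher, 79 lower) and 33 without 80 mg/kg replicate 1. Leaving out any single array except 80 mg/kg replicate 3 ended the call of at least 1 of Fancd2os, Cxcl9, Pla2g2a, Cyp26b1, Slc22a3, Lox and Fn1 (adjusted p up to 0.339, 0.0826, 0.0625, 0.0908, 0.261, 0.146 and 0.182).

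**Figure D1:**
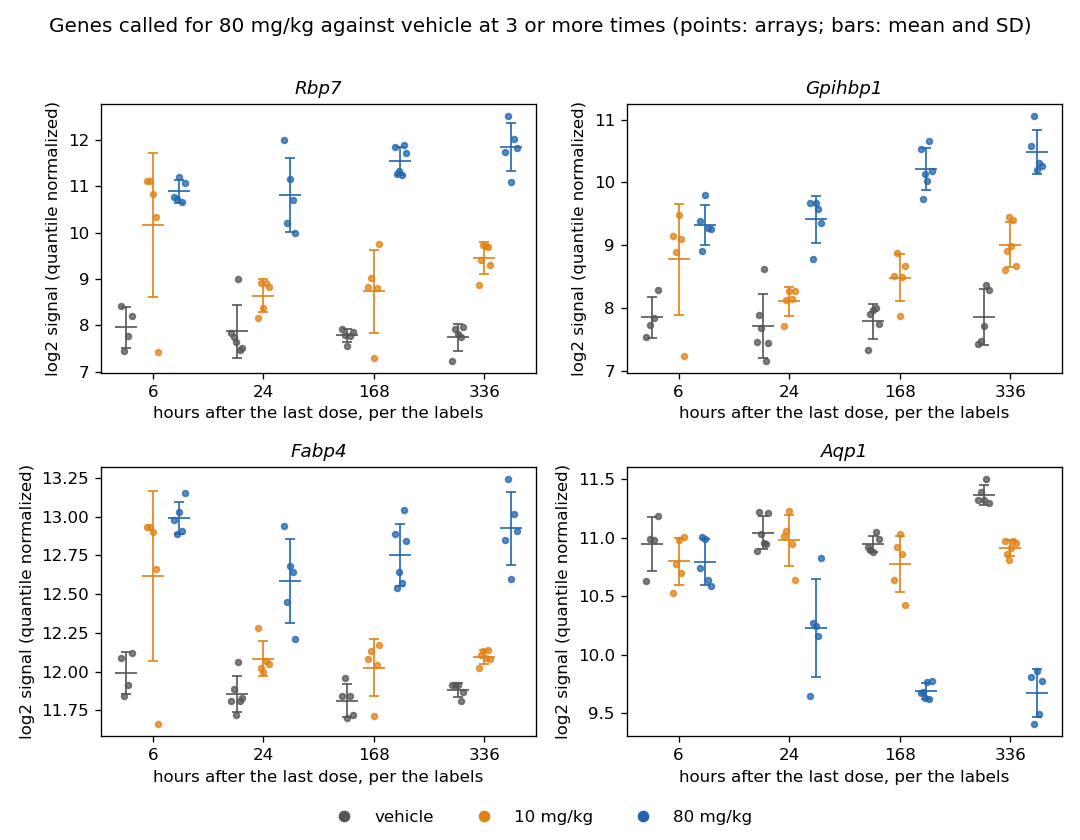
Log2 signal of Rbp7, Gpihbp1, Fabp4 and Aqp1 against sampling time in hours after the last dose, with a point per array and group means with SD for vehicle, 10 mg/kg and 80 mg/kg. At 336 h the means at 80 mg/kg and in vehicle were 11.84 and 7.74 for Rbp7 and 9.67 and 11.37 for Aqp1.

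Over the 4 times at 80 mg/kg, Rbp7, Gpihbp1 and Fabp4 were called at each, Aqp1 and Hrct1 at 3. Of 81 probe sets called at any time 11 were called at 2 or more, and 0 of these changed sign. Within the array clusters that held both groups at a time, each of the 8 differences of Rbp7 (2.82 to 4.1), Gpihbp1 (1.33 to 3.27), Fabp4 (0.795 to 1.12) and Aqp1 (−1.7 to −0.144) had the sign of the pooled value. These genes were called from the same arrays, so this is not a separate test. At 336 h all arrays lay in 1 cluster, so that value was the pooled one, and some others rested on 1 array on a side. Of the other genes called at 2 or more times, Fabp5, Hrct1 and Ggta1 had 8 of 8 values of 1 sign, Slc2a3 7 and Afdn 6. The size of the 80 mg/kg effect differed between times for 4 genes by a moderated F test, with 1359 probe sets at an unadjusted p under 0.05. Relative to the effect at 6 h, that on Aqp1 was −0.66, −1.10 and −1.54 at 24, 168 and 336 h (adjusted p = 4.82e-06) and that on Bhlhe41 0.95, −0.06 and −0.43 (adjusted p = 0.000126). That on Akap12 was −0.18, 0.53 and 1.05 (adjusted p = 0.00264) and on Ccn2 0.52, 0.99 and 1.62 (adjusted p = 0.00703). Rbp7, Gpihbp1 and Fabp4 were not among them. The count of 4 was 0 on the deposited scale, 7 without vehicle replicate 3 of 6 h or replicate 2 of 168 h, 10 with 1 probe set per gene, 12 with control probe covariates and 23 with array weights.

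**Figure D2:**
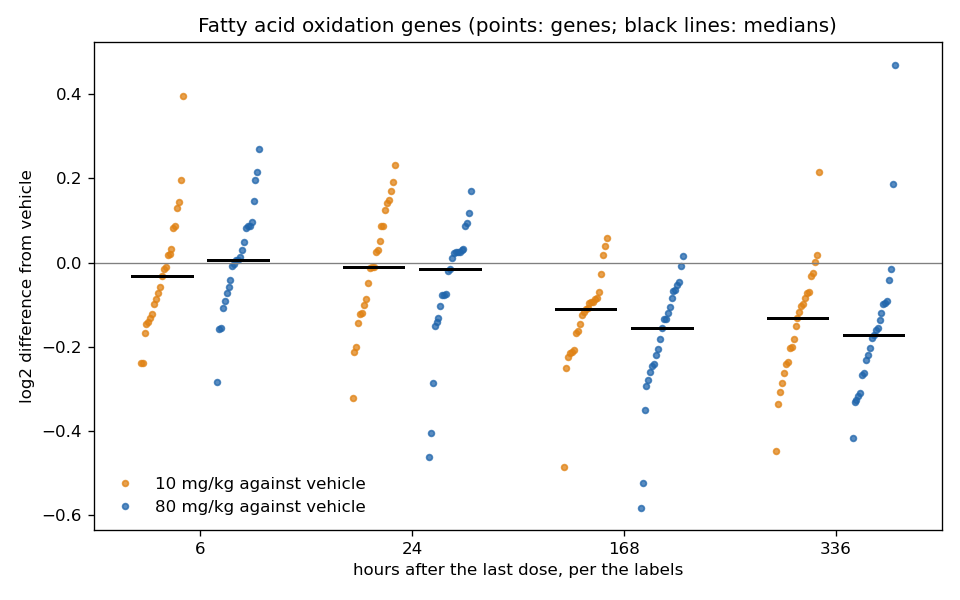
Log2 difference from vehicle of each measured gene of fatty acid oxidation against sampling time in hours, for 10 and 80 mg/kg, with the median marked. At 168 h the 80 mg/kg values ran from −0.58 to 0.01 and at 336 h from −0.41 to 0.47, relative to the other genes on the arrays.

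At 10 mg/kg limma called 0 probe sets against vehicle at each of the 4 times, with 1196, 1088, 718 and 676 at an unadjusted p under 0.05 at 6, 24, 168 and 336 h. The genes called at 80 mg/kg mostly lay in the same direction. Rbp7 differed from vehicle by 2.21, 0.77, 0.96 and 1.71 (adjusted p = 0.0652, 0.852, 1 and 0.414) and Gpihbp1 by 0.92, 0.39, 0.69 and 1.15. Fabp4 differed by 0.63, 0.23, 0.22 and 0.21 (adjusted p = 0.157, 0.858, 1 and 1) and Aqp1 by −0.15, −0.06, −0.17 and −0.45. These p-values rest on 1 spread per probe set over all 12 groups, among them 10 mg/kg at 6 h with an SD of 1.56 for Rbp7. At 336 h Fabp4 averaged 12.1 ± 0.04 (SD, n = 6) at 10 mg/kg and 11.88 ± 0.04 (SD, n = 5) in vehicle. Aqp1 averaged 10.92 ± 0.07 and 11.37 ± 0.08, and Rbp7 9.45 ± 0.34 and 7.74 ± 0.29. The genes were picked at 80 mg/kg against the same vehicle arrays. Lack of a call there thus does not show lack of a difference. In the 10 mg/kg group of 6 h, Rbp7 lay between 10.3 and 11.1 in 4 arrays and at 7.43 in replicate 5. At 6 h the count was 6 without vehicle replicate 3, 5 without 10 mg/kg replicate 5, and 1 without vehicle replicate 5 or 6. It was 1 on the deposited scale, with the strict filter, with 1 probe set per gene, with the array cluster as a block or with control probe covariates. It was 21 without the high-Myl7 arrays, which left a single 10 mg/kg array that is assumed to vary like the other groups. At 24 h it was 2 without vehicle replicate 2 and 1 without vehicle replicate 4. At 168 h it was 1 without vehicle replicate 3 or 10 mg/kg replicate 2 or 3, on the deposited scale, with array weights, with the array cluster as a block, with control probe covariates and without the high-Myl7 arrays. At 336 h it was 5 with array weights, 2 without the high-Myl7 arrays, and 1 without vehicle replicate 6 and with the 336 h arrays alone.

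Several gene lists were called at 10 mg/kg although single genes were not. Genes of fatty acid oxidation were lower at 168 h (20 of 23 negative, median −0.11, camera adjusted p = 4.68e-05; adjusted p = 0.25 with an estimated correlation). They were lower at 336 h too (20 of 23 negative, median −0.13, adjusted p = 3.67e-08; adjusted p = 0.123 with an estimated correlation). There Eci1, Acadm, Decr1 and Acadvl passed adjusted over the list alone, with Decr1 at −0.45. Extracellular matrix genes were higher at 336 h, with 29 of 29 positive (median 0.13, adjusted p = 0.000104; adjusted p = 0.606 with an estimated correlation). So was the fetal gene program and wall stress list (14 of 15 positive, median 0.17, adjusted p = 0.00847; adjusted p = 0.318 with an estimated correlation), the latter not on the deposited scale (0.166). The peroxisome and classical PPAR target list was lower at 336 h (11 of 18 negative, median −0.07, adjusted p = 0.0204; adjusted p = 0.134 with an estimated correlation). This was lost on the deposited scale (0.197) and without vehicle replicate 3 or 6 or 10 mg/kg replicate 2 (up to 0.0545). At 168 h heat shock and unfolded protein genes were higher (17 of 19 positive, median 0.08, adjusted p = 0.0124; adjusted p = 0.25 with an estimated correlation). The call was lost on the deposited scale (0.183) and without vehicle replicate 1 or 3 or 10 mg/kg replicate 5 (up to 0.147). At 24 h adipocyte markers were higher (10 of 13 positive, median 0.29, adjusted p = 0.00533; adjusted p = 0.29 with an estimated correlation). That call rested on 10 mg/kg replicate 1 (0.703 without it). Clock genes at 24 h had 11 of 15 positive (median 0.10, adjusted p = 0.0481; adjusted p = 0.134 with an estimated correlation), with 2, Bhlhe41 and Bhlhe40, passing adjusted over the list alone. The list was lost without vehicle replicate 2 or 3 or 10 mg/kg replicate 2, 3 or 5 (up to 0.152) and with probe sets averaged per gene (0.168). At 6 h the atrial list was higher (7 of 7 positive, median 0.88, adjusted p = 0.00772; adjusted p = 0.507 with an estimated correlation), with Myl7 high in 4 of the 5 treated arrays. It was lost without vehicle replicate 1, 3 or 5 or 10 mg/kg replicate 4 (up to 0.179). It was also lost with probe sets averaged per gene (0.0527) and with the replicate number as a block (0.0571). On the deposited scale the medians of the adipocyte marker, clock, heat shock and peroxisome lists were −0.07, −0.20, −0.17 and 0.08, opposite in sign, beside −0.36, −0.36, −0.25 and 0.14 for all probe sets at those times. In these lists 0 members passed limma over all probe sets, and where none is named 0 passed adjusted over the list alone.

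The doses were also compared with each other. At 336 h Rbp7 was 2.39 higher at 80 than at 10 mg/kg (SE 0.38, adjusted p = 0.000227), Gpihbp1 1.47 (SE 0.26, adjusted p = 0.00097) and Fabp4 0.83 (SE 0.13, adjusted p = 0.000194). Akap12 was 0.96 higher (SE 0.14, adjusted p = 5.42e-05), Plpp1, a phospholipid phosphatase, 0.94 (SE 0.12, adjusted p = 2.73e-06), Tubb2b, a tubulin, 0.91 (SE 0.17, adjusted p = 0.00335) and Tnfsf10 0.86 (adjusted p = 0.00231). Aqp1 differed by −1.24 (SE 0.12, adjusted p = 7.22e-10) and Myrip by −0.78 (SE 0.14, adjusted p = 0.00244). At 168 h Rbp7 was 2.80 higher (SE 0.38, adjusted p = 1.53e-05), Gpihbp1 1.73 (SE 0.26, adjusted p = 7.96e-05) and Fabp4 0.73 (SE 0.13, adjusted p = 0.00404). Plpp1 was 0.63 higher (SE 0.12, adjusted p = 0.00905) and Aqp1 differed by −1.08 (SE 0.12, adjusted p = 7.73e-08). At 24 h Rbp7 was 2.18 higher (SE 0.40, adjusted p = 0.0139) and Aqp1 differed by −0.75 (SE 0.13, adjusted p = 0.00522). All arrays at 80 mg/kg lay on the same side of the 10 mg/kg mean for each. The counts were 0 at 6 h (limma, 686 at an unadjusted p under 0.05), 2 at 24 h (1 higher, 1 lower), 7 at 168 h (6 higher, 1 lower) and 19 at 336 h (17 higher, 2 lower). On the deposited scale they were 0, 1 (1 higher), 3 (3 higher) and 3 (2 higher, 1 lower). The 6 h count was 18 without the high-Myl7 arrays. It was 1 without 10 mg/kg replicate 5 or 80 mg/kg replicate 1, with the strict filter, with 1 probe set per gene and with the array cluster as a block. The 24 h count was 0 without 10 mg/kg replicate 3, without 80 mg/kg replicate 2 or with the compared arrays alone (644 at an unadjusted p under 0.05). It was 1 without 10 mg/kg replicate 1 or 80 mg/kg replicate 4 or with the Myl7 level as a covariate and 4 without 80 mg/kg replicate 6. It was 5 with 1 probe set per gene or without the high-actin arrays, and 8 without the high-Myl7 arrays. Rbp7 and Aqp1 reached adjusted p of 0.284 and 0.153 without 80 mg/kg replicate 2. At 168 h Fabp4 (0.0642) and Plpp1 (0.0955) were lost without 10 mg/kg replicate 4, and Plpp1 also without 10 mg/kg replicate 5 or 80 mg/kg replicate 1 or 5. The 336 h count was 50 with array weights and 30 with the array cluster as a block.

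Between the doses at 336 h the adipocyte cell type list was higher at 80 mg/kg (4 of 5 positive, median 0.41, camera adjusted p = 0.000528; adjusted p = 0.0536 with an estimated correlation). Passing were Fabp4 over all probe sets and Fabp4 and the glycerol channel Aqp7 adjusted over the list alone. Adipocyte markers (9 of 13 positive, median 0.10, adjusted p = 0.00873; adjusted p = 0.318 with an estimated correlation) had the same members passing, since both lists hold Fabp4 and Aqp7 (1 over all probe sets, 2 adjusted over the list alone). Cell cycle genes were higher (17 of 21 positive, median 0.22, adjusted p = 0.00196; adjusted p = 0.364 with an estimated correlation), though not without 80 mg/kg replicate 4 (0.074). At 24 h the atrial list was higher (6 of 7 positive, median 1.32, adjusted p = 0.000172; adjusted p = 0.261 with an estimated correlation), with 0 members passing limma over all probe sets and 3 adjusted over the list alone. So was the fetal gene program and wall stress list (12 of 15 positive, median 0.04, adjusted p = 0.00653; adjusted p = 0.29 with an estimated correlation), a call lost without 10 mg/kg replicate 6 or 80 mg/kg replicate 4 (up to 0.114). In the cell cycle list and the fetal list 0 members passed limma over all probe sets and 0 adjusted over the list alone. Nppa belongs to both the atrial and the fetal list, and Myl7 was high in 3 of the 5 arrays at 80 mg/kg and 0 of those at 10 mg/kg. At 6 h immediate early genes were higher (11 of 12 positive, median 0.40, adjusted p = 0.00499; adjusted p = 0.605 with an estimated correlation), lost without 80 mg/kg replicate 4, 5 or 6 (up to 0.138). Fatty acid uptake and storage genes were higher at 6 h (16 of 21 positive, median 0.09, adjusted p = 0.05; adjusted p = 0.472 with an estimated correlation). This was lost without 10 mg/kg replicate 1, 2 or 5 or 80 mg/kg replicate 1, 2 or 4 (up to 0.349), on the deposited scale (0.101) and with probe sets averaged per gene (0.11). The atrial list was lower at 6 h (7 of 7 negative, median −0.64, adjusted p = 0.0434; adjusted p = 0.66 with an estimated correlation). This was lost without 10 mg/kg replicate 1, 3 or 4 or 80 mg/kg replicate 1, 5 or 6 (up to 0.603). It was also lost with no filter (0.0509), with probe sets averaged per gene (0.0867) and with the replicate number as a block (0.0679). In these 3 lists at 6 h 0 members passed limma over all probe sets and 0 adjusted over the list alone.

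No probe set was called at both doses at any time (0 at each of the 4 times in limma, with 0 from independent lists), except for 1 at 6 h on the deposited scale. Of the probe sets called at 80 mg/kg, 10 of 10, 25 of 26, 10 of 10 and 53 of 54 had the same sign at 10 mg/kg, or 100%, 96.2%, 100% and 98.1%. Unchanged groups sharing the vehicle arrays gave 99%, 94.6%, 98.4% and 96.8% for as many probe sets of largest difference relative to their residual SD. The real shares therefore do not part an effect of 10 mg/kg from the shared vehicle arrays. With the vehicle arrays split between the doses before as many probe sets were chosen, the mean shares were 65%, 76.2%, 76% and 73.1%. The correlations of the differences at both doses, taken across probe sets that are not independent replicates, were 0.675, 0.627, 0.501 and 0.605. Unchanged groups sharing the vehicle arrays gave 0.547, 0.456, 0.514 and 0.513, and the vehicle arrays split between the doses gave 0.0454, 0.217, −0.0464 and 0.135. The covariances were 0.0601, 0.0533, 0.0318 and 0.0354, beside simulated means of 0.0442, 0.0303, 0.0353 and 0.0356 with residuals of all times and of 0.0548, 0.0338, 0.0419 and 0.0257 with residuals of the same time. Each lay within the central 95% of both simulations, which ran from 0.0222 to 0.0798, 0.0131 to 0.0614, 0.0153 to 0.0657 and 0.0167 to 0.0674 for all times and from 0.0128 to 0.111, 0.0057 to 0.0698, 0.0152 to 0.0853 and 0.0115 to 0.0367 for the same time. With split vehicle arrays the mean covariances were 0.00596, 0.0242, −0.005 and 0.0112. Over the splits the median of the fatty acid oxidation genes at 168 and 336 h was at most −0.107 and −0.149 for 80 mg/kg and at most −0.0863 and −0.113 for 10 mg/kg.

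Among the metabolic and cardiac genes reported whatever their p, only Fabp4 was called in any comparison with vehicle. At 80 mg/kg against vehicle at 6, 24, 168 and 336 h, the fatty acid transporter Cd36 differed by 0.55, 0.51, 0.29 and 0.35 (adjusted p = 0.489, 0.281, 0.976 and 0.751). The natriuretic peptide gene Nppa, which is also atrial, differed by 0.31, 1.71, 0.91 and 1.25 (SE 0.67, 0.60, 0.60 and 0.63, adjusted p = 0.954, 0.291, 0.996 and 0.722), and Nppb by −0.78, 0.46, 0.41 and 0.49. Pdk4, the kinase that shuts off pyruvate oxidation, was at 0.02, −0.49, −0.49 and −0.02. Cpt1a, a carnitine palmitoyltransferase, was at 0.27, −0.29, −0.16 and −0.09, and the uncoupling protein Ucp3 at 0.70, −1.66, −0.24 and −0.07 (adjusted p = 0.11 at 24 h). Pparg itself, the gene of the drug's receptor, was at 0.41, 0.06, 0.38 and 0.46, Ppara at −0.45, 0.32, 0.26 and −0.05, and Ppard at 0.09, 0.13, 0.14 and −0.03. The fetal myosin Myh7 was at −0.53, −0.51, 0.83 and 0.64, the collagen Col1a1 at 0.11, 0.17, 0.19 and 0.18, and the insulin-responsive glucose transporter Slc2a4 at 0.24, 0.01, 0.15 and 0.02.

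In vehicle animals levels also differed between sampling times, with clock genes among the smallest p-values. By the labels 24, 168 and 336 h lie whole days after the final dose and 6 h does not. The 6 h arrays may therefore differ from the later ones in time of day as well as in age. The labels give no clock time, and neither was tested. Relative to 6 h, Bhlhe41 was −1.16, −1.29 and −1.06 at 24, 168 and 336 h (moderated F test adjusted p = 1.42e-07) and the clock repressor Nr1d2 −0.98, −1.30 and −1.62 (adjusted p = 2.12e-05). Arrdc3 was −0.91, −0.90 and −1.21 (adjusted p = 5.27e-06) and Jade1 −0.31, −0.44 and −0.83 (adjusted p = 4.33e-06). G0s2, an inhibitor of lipolysis, was 1.29, 1.41 and 1.35 (adjusted p = 5.3e-06), and Slc41a3, a magnesium transporter, 0.80, 0.89 and 1.06 (adjusted p = 5.3e-06). The sarcomere gene Ttn was 0.10, −0.00 and −0.39 (adjusted p = 1.33e-05) and the growth factor Igf1 0.25, 0.17 and −0.60 (adjusted p = 3.23e-05, or 0.0606 with the array cluster as a block). The test called 1499 probe sets, with 4759 at an unadjusted p under 0.05. It called 53 with the array cluster as a block, 50 of them among the 1499, and 10 on the deposited scale. All vehicle arrays of 336 h lay in 1 cluster. The count was 791, 842, 699 and 976 without replicate 3, 4, 5 and 6 of that group. It was 834 with no filter, 3584 with array weights, 969 with 1 probe set per gene, 942 without the high-Myl7 arrays, 982 without the high-actin arrays and 802 with vehicle arrays alone. For the effect of 10 mg/kg, limma found 0 probe sets that differed between times (875 at an unadjusted p under 0.05), with 1 without vehicle replicate 3 or 6 of 6 h and 6 without the high-Myl7 arrays.

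**Figure D3:**
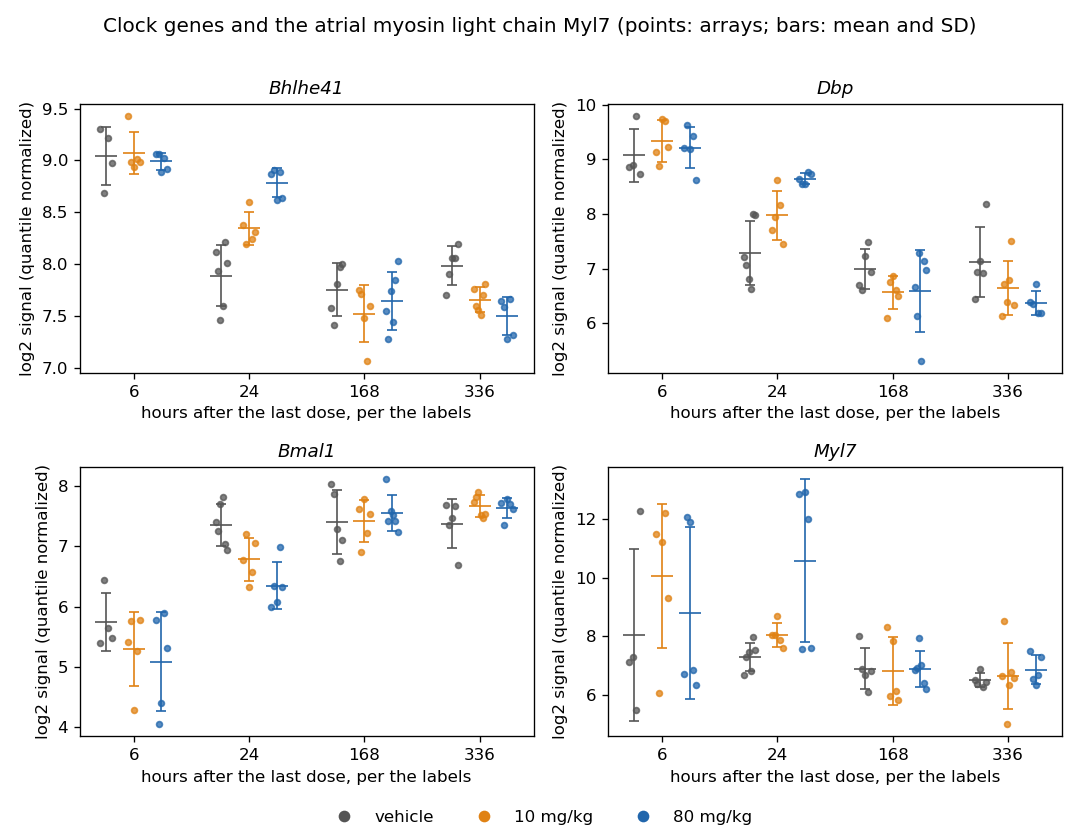
Log2 signal of the clock genes Bhlhe41, Dbp and Bmal1 and of the atrial gene Myl7 against sampling time in hours after the last dose, with a point per array and group means with SD for vehicle, 10 mg/kg and 80 mg/kg. At 24 h Bhlhe41 averaged 7.89 in vehicle, 8.35 at 10 mg/kg and 8.78 at 80 mg/kg, while over all times 10 arrays stood above 9 for Myl7, 3 of them at 24 h.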

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

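The tests of explanations in this part were chosen only after the results had been seen. The checks for single arrays far from the rest of their group were planned.

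For the 9 genes called at 2 or more times at 80 mg/kg, 11 of 108 gene and group combinations held an array whose gap to the nearest other array was large against the range of its group, where chance marks about 1 in 20 groups (5.4 here). At 10 mg/kg and 6 h replicate 5 stood apart for 3 genes, with Rbp7 at 7.43 (others 10.3 to 11.1), Gpihbp1 at 7.24 (others 8.9 to 9.48) and Fabp4 at 11.7 (others 12.7 to 12.9). At 10 mg/kg and 24 h replicate 1 had Fabp4 at 12.3 (others 12 to 12.1) and Gpihbp1 at 7.72 (others 8.13 to 8.27). At 10 mg/kg replicate 4 had Fabp4 at 11.7 at 168 h (others 12 to 12.2), where it was also lowest for Rbp7 (7.29, others 8.81 to 9.76) and Gpihbp1 (7.88, others 8.50 to 8.88), without passing that limit. Replicate 4 of 336 h at this dose had Fabp5 at 10.2 (others 9.87 to 9.98). In vehicle at 24 h replicate 4 had Rbp7 at 9 (others 7.48 to 7.84). At 80 mg/kg Ggta1 was at 8.16 in replicate 3 of 24 h (others 8.51 to 8.55) and at 8.23 in replicate 3 of 336 h (others 8.73 to 8.91), and Afdn was at 7.97 in replicate 2 of 336 h (others 8.26 to 8.31).

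The 80 mg/kg effect differed between sampling times for Aqp1 (adjusted p = 4.82e-06), Bhlhe41 (0.000126), Akap12 (0.00264) and Ccn2 (0.00703) by limma's moderated F test.

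Replicate 5 of 10 mg/kg at 6 h lacked the rise of Rbp7 seen in the other 4 arrays of its group. Poor array quality is argued against by the measures at hand. Its mean rank correlation with the other arrays (0.932) lay within the range of the others of its group (0.896 to 0.932). Its hexokinase 3' to 5' difference of 3.76 was the highest of its group. In the 2 other treated arrays of 6 h with at least as high a difference (4.22 and 3.78) Rbp7 was at 10.7 and 10.8, against at most 8.42 in vehicle. Both of these arrays were at 80 mg/kg, so the dose differed from that of replicate 5. A response score was taken over the 7 probe sets called for 80 mg/kg at 6 h other than those of Rbp7, Gpihbp1 and Fabp4. It ran from −0.092 to 0.137 in the vehicle arrays of 6 h, against which those probe sets had been called. In replicate 5 it was 0.363, and it was 0.399 to 1.01 in the other arrays of its group. The ratio of 0.498 to the mean of the others (0.22 with Gpihbp1 and Fabp4, which had marked this array, among 9 probe sets) does not decide on an animal with little drug exposure or a wrong label, which stays open. An animal that did not respond to the dose may give the same values and was not tested.

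More probe sets were called at 80 mg/kg against vehicle at 336 h (54) than at 6 h (10), while the median residual SD was 0.231 at 336 h and 0.295 at 6 h. For the 4 probe sets whose effect differed between times, each difference moved from 6 to 336 h by at least 2.33 times its standard error from those groups. Aqp1 went from −0.155 to −1.70 and Ccn2 from −0.64 to 0.98, with a change of sign. Bhlhe41, not called at 336 h, went from −0.053 to −0.486. The 4 were chosen for such a difference in the same arrays, so this does not separately test a lower spread at 336 h alone. For the count as a whole it cannot be told apart from a larger effect, because the ratio of the mean difference at 336 h to that at 6 h was 1.21 (SE 0.356) for 32 probe sets called at 24 or 168 h, and settings that let the spread differ moved the counts further apart (232 and 5 with array weights, 52 and 0 with only the arrays compared). An additive difference between array clusters is argued against as the whole source for Aqp1, whose effect still differed between times with the cluster as a block (adjusted p = 4.74e-06). A lasting effect of the dose stays open, untested, and would rest on the sampling times being hours after the final dose, as the labels state.

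Clock genes differed between 80 mg/kg and vehicle at 24 h, with the list call lost at an estimated correlation (adjusted p = 0.0649). Atrial tissue in some arrays is argued against as the whole source by the arrays without high Myl7 (2 at 80 mg/kg, 6 of vehicle). Among these Bhlhe41 still differed by 0.884 (SE 0.23), Bhlhe40 by 1.81 (SE 0.401) and Dbp by 1.36 (SE 0.435). The 3 genes had been called in a comparison that included these arrays, which favours such differences, and only 2 of the arrays were treated. Dbp lost its call with the Myl7 level as a covariate (1.29, limma adjusted p = 0.105) and without the high-Myl7 arrays (adjusted p = 0.211). An additive difference between array clusters is argued against as the whole source for Bhlhe41, at 0.923 (SE 0.158) of its difference with the cluster as a block, and for Dbp (0.971, SE 0.215), although Dbp lost its call there with nearly the same difference (1.32 against 1.36, adjusted p = 0.0542), and it stays open for Bhlhe40 (0.587, SE 0.173), which fell from 1.44 to 0.84 (adjusted p = 0.262). Dissection at another time of day may give such a pattern: across the 15 genes, which are not independent, the differences correlated with those between 6 and 24 h at 10 mg/kg (r = 0.562, Spearman 0.468, 0.427 to 0.707 leaving out each gene, 10 of the same sign). At 10 mg/kg Myl7 was high in 4 of the 5 arrays of 6 h and in 0 of 24 h. At 24 h it was high in 3 of the 5 arrays at 80 mg/kg and in 0 of vehicle. Atrial tissue may thus enter both sets of differences, so their correlation does not bear on time of day alone. Clock time is not among the labels, so dissection at another time of day cannot be told apart from an effect of the dose on the clock, which stays open.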

How the results depend on the processing

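Median scaling, the array cluster block, both covariate settings and the removal of arrays with high Myl7 or high actin difference were chosen after seeing the data, and all other alternatives were planned. No called result of a named gene turned its direction under the settings run for it, single arrays left out included, nor did the camera direction of a called list under the settings run for it. Counts near the threshold moved much more than the leading genes did, and the cause was not tested except where fewer arrays or fewer probe sets entered by construction. Low signal limits the precision for genes of low level, and the number of arrays limits the precision of all differences.

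Of the 61 called results of named genes, 20 were kept on the deposited scale, 48 with no filter, 48 of 48 with the strict filter, 59 with the pseudocount, 55 with array weights, 59 with the trended robust prior, 53 with median scaling, 51 with the cluster block, 48 with control probe covariates, 51 with the Myl7 covariate, 44 without high-Myl7 arrays, 46 without high-actin arrays, 31 with only the arrays compared, and 31 on leaving out every array in turn. Of the 27 called lists, 0 were kept with an estimated correlation, 5 with fry, 23 on the deposited scale, 24 with no filter, 20 with probe sets averaged per gene and 27 with the cluster block.

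Counts are given where they moved by over 1.5 times, at 6, 24, 168 and 336 h for 80 mg/kg against vehicle (10, 26, 10 and 54 in the main setting), 10 mg/kg against vehicle (0 at each) and 80 against 10 mg/kg (0, 2, 7 and 19), then for the effect of 80 mg/kg over time (4), that of 10 mg/kg (0) and vehicle over time (1499). On the deposited scale, with limma as throughout, 80 mg/kg against vehicle gave 6, 1, 3 and 5, 10 mg/kg 1 at 6 h and 1 at 168 h, 80 against 10 mg/kg 1, 3 and 3 at 24, 168 and 336 h, the effect of 80 mg/kg over time 0, vehicle 10, and 1 probe set was called by both doses at 6 h. With no filter, 80 mg/kg gave 5 at 6 h and 6 at 168 h, and vehicle 834. With the strict filter, 10 mg/kg gave 1 and 80 against 10 mg/kg 1, both at 6 h. With array weights, 80 mg/kg gave 5, 48 and 232 at 6, 24 and 336 h, 10 mg/kg 1 at 168 h and 5 at 336 h, 80 against 10 mg/kg 50 at 336 h, the effect of 80 mg/kg over time 23, and vehicle 3584, with mean weights of 0.96, 0.974, 0.889 and 1.42 at the 4 times. With 1 probe set per gene, 10 mg/kg gave 1 at 6 h, 80 against 10 mg/kg 1 at 6 h and 5 at 24 h, the effect of 80 mg/kg over time 10, and vehicle 969. With only the arrays compared, 80 mg/kg gave 0 at 6 h (897 at an unadjusted p under 0.05) and 6 at 24 h, 10 mg/kg 1 at 336 h, 80 against 10 mg/kg 0 at 24 h (644 at an unadjusted p under 0.05), and vehicle 802.

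Median scaling gave 214 for 80 mg/kg at 24 h. With the array cluster as a block, 80 mg/kg gave 16, 12 and 19 at 6, 24 and 168 h, 10 mg/kg 1 at 6 h and 1 at 168 h, 80 against 10 mg/kg 1 at 6 h and 30 at 336 h, and vehicle 53. Control probe covariates gave 11 for 80 mg/kg at 24 h, 1 for 10 mg/kg at 6 h and 1 at 168 h, and 12 for the effect of 80 mg/kg over time. The Myl7 covariate gave 11 for 80 mg/kg and 1 for 80 against 10 mg/kg, both at 24 h. Without the 10 high-Myl7 arrays, 80 mg/kg gave 5 at 6 h, 10 mg/kg 21, 1 and 2 at 6, 168 and 336 h, 80 against 10 mg/kg 18 at 6 h and 8 at 24 h, the effect of 10 mg/kg over time 6, and vehicle 942. This left 1 array at 10 mg/kg and 6 h, which is assumed to vary like the other groups. Without the 3 high-actin arrays, 80 mg/kg gave 6 at 6 h and 8 at 24 h, 80 against 10 mg/kg 5 at 24 h, and vehicle 982.

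Leaving out each array in turn, the counts for 80 mg/kg ran from 3 (without 80 mg/kg replicate 1) to 29 (vehicle replicate 3) at 6 h, from 7 (80 mg/kg replicate 2) to 46 (vehicle replicate 2) at 24 h, from 5 (vehicle replicate 5) to 12 at 168 h and from 33 (80 mg/kg replicate 1) to 66 at 336 h. Those for 10 mg/kg ran from 0 to 6 (vehicle replicate 3), 0 to 2 (vehicle replicate 2), 0 to 1 (vehicle replicate 3 among others) and 0 to 1 (vehicle replicate 6). Those for 80 against 10 mg/kg ran from 0 to 1 (10 mg/kg replicate 5 or 80 mg/kg replicate 1), 0 (10 mg/kg replicate 3 or 80 mg/kg replicate 2) to 4 (80 mg/kg replicate 6), 5 to 8 and 13 to 27. For the effect of 80 mg/kg over time they ran from 4 to 7, for 10 mg/kg from 0 to 1 and for vehicle from 699 (replicate 5 of 336 h) to 2017.

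Samples with the same replicate number were treated as unpaired. Deviations of 52 same-numbered pairs correlated at a mean of 0.0173 (−0.257 to 0.338, 14 over 0.1), against −0.00328 in 268 other pairs. This was not tested and does not exclude a pairing of some of them. With the replicate block, 80 against 10 mg/kg gave 1 at 6 h and the effect of 80 mg/kg over time 7, no other count moved by over 1.5 times, and 57 of 61 named gene calls and 24 of 27 list calls were kept.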

Other observations

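The splits of the arrays reported in this part were planned, and the genes in the opening paragraph that the rule for named genes does not take were chosen after their values were seen. At 336 h further genes were called at 80 mg/kg. Kdr, the main receptor for vascular endothelial growth factor, rose by 0.48 (limma adjusted p = 0.00401), F2r, the thrombin receptor, by 0.76 (adjusted p = 8.74e-06), Ccm2l, an endothelial gene, by 0.97 (adjusted p = 0.00488), Nid1, a basement membrane protein, by 0.66 (adjusted p = 0.0193) and the monoglyceride lipase Mgll by 1.01 (adjusted p = 0.00225). The endothelial list as a whole was not called, with 7 of 12 members positive (median 0.10, adjusted p = 0.371), Kdr passing over all probe sets and Kdr and Tek adjusted over the list alone. Slc2a3 differed by 1.21, 0.15, 0.55 and 0.88 at 6, 24, 168 and 336 h, Fabp5 by 0.60, 0.21, 0.78 and 0.82 and Hrct1 by 0.61, 0.12, 0.51 and 0.56. At 24 h the detoxifying hydrolase Ephx1 rose by 0.88 (adjusted p = 0.0187) and the sarcomere gene Tcap by 0.55 (adjusted p = 0.0253), while Eno3, the muscle enolase, fell by 0.59 (adjusted p = 0.0231). With the array cluster as a block the limma adjusted p was 0.00371 for Ephx1, but 0.202 for Tcap and 0.0807 for Eno3. Myl7 was high in 3 of the treated arrays and 0 of the vehicle arrays of 24 h. At 336 h the lipid droplet gene Plin2 was 0.38 higher at 80 than at 10 mg/kg (adjusted p = 0.0439).

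The remaining gene lists were called by camera in none of the 12 comparisons. The sodium, water and volume list came nearest, at an adjusted p of 0.0622 for 80 mg/kg against vehicle at 336 h (median −0.12), with Aqp1 its 1 member called lower over all probe sets. The smallest adjusted p was 0.101 for cardiomyocytes, 0.137 for fibroblasts, 0.137 for ketone metabolism and uncoupling, 0.16 for macrophages and monocytes, 0.278 for oxidative phosphorylation, 0.334 for mesothelium, 0.371 for endothelium, 0.392 for skeletal muscle, 0.407 for neutrophils and mast cells, 0.407 for oxidative stress, 0.463 for nerve, 0.477 for smooth muscle, 0.477 for antigen presentation and lymphocytes, and 0.502 for glucose use.

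Other groupings of the same arrays were drawn, 100 per count with the real one included. For 80 mg/kg against vehicle, 3, 2, 1 and 1 of them at 6, 24, 168 and 336 h called as many probe sets as the real grouping. The real counts were 10, 26, 10 and 54, and the highest others 65, 519, 9 and 8. The real count thus exceeded all others drawn at 168 and 336 h, but not at 6 and 24 h. Each count was judged alone, with no correction for the number of counts, so shares this small do not exclude chance. For 10 mg/kg against vehicle the real count was 0, which any grouping reaches (100 of 100), so the comparison says nothing there, and the highest others were 136, 796, 9 and 2. For 80 against 10 mg/kg, 100, 19, 4 and 1 groupings reached the real counts of 0, 2, 7 and 19, with the highest others at 59, 693, 42 and 2. The real count there exceeded all others drawn only at 336 h, and the count of 0 at 6 h again says nothing. Over time, 2 groupings reached the 4 probe sets of 80 mg/kg (highest other 29), 100 the 0 of 10 mg/kg, as any would (highest other 14), and 1 the 1499 of vehicle (highest other 1209). For vehicle over time the real count exceeded all others drawn, and for 80 mg/kg over time it did not. Groupings that called at least 3 times the real count numbered 1, 1, 0 and 0 for 80 mg/kg, 16, 8, 7 and 0 for 10 mg/kg (at least 3 probe sets) and 6, 13, 1 and 0 for 80 against 10 mg/kg, and point to a structure of the arrays whose nature was not tested.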
